A study of Arabidopsis thaliana with 8 samples.

How the data were processed

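Total RNA of the Arabidopsis thaliana triple mutant myc2,3,4 and of its wild type Col-0 was compared on 8 Agilent 2-colour arrays, 4 with RNA of plants in white light (WL) and 4 with RNA of plants in WL with added far red (FR). Per the labels, the far red was added for 3 h in FR and not at all in WL. The labelled ratio of red to far red was lower in FR than in WL. Light intensity, growth temperature, photoperiod (8 h of dark) and stratification (3 days at 4 degrees C) were labelled alike for both. Every array held 1 mutant and 1 Col-0 sample of the same light. By the labels, 200 ng of RNA was amplified per sample, and Hyper5 (the red dye) marked Col-0 on replicates 1 and 3 of each light and the mutant on replicates 2 and 4. Tissue, plant age and hour of harvest were not given in the sources used here, and whether replicates were separate plant samples or repeat hybridizations was not given either. The p-values therefore measure only the spread between these samples.

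Per the file headers, the authors' scans were read with Feature Extraction 10.7.3.1 (protocol GE2_107_Sep09, design 021169), which gave for each spot the mean signal and the median local background of each dye as intensity values with no normalization. The same deposited scanner files held processed signals, which per the file headers were background-subtracted and dye-normalized intensity values, and a ratio of red over green on the log10 scale. A deposited matrix of the whole series held 1 log2 ratio per probe and array, with its processing not given in the sources used here. It was checked against the scanner values over 12387 bright spots. Its sign followed myc2,3,4 over Col-0 on all 8 arrays, array medians lay between -0.02 and 0.02, and its values correlated at r = 0.997 to 0.999 with log2 ratios quantile normalized within each light. Slopes were 0.990 to 0.998 against those ratios but 0.941 to 0.945 in FR and at least 1.04 in WL against ratios normalized over all 8 arrays, so the deposited matrix was used only as an alternative.

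Values were recomputed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Mean signals were corrected for the local background with normexp (offset 50), and log2 ratios were normalized by loess within each array. Each array carried 45220 spots, of which 1417 were controls and took no part in the loess curve. Spots that the scanner software marked as non-uniform or as population outliers (0.228% to 1.49% of gene spots per array) were left out, and 0 probes were saturated. Ratios were turned so that a positive value means more signal in myc2,3,4. Of 43603 probes, 34244 were named through a RefSeq accession of the reference table (assembly TAIR10.1), 1073 through a locus code and 549 through a symbol. A further 498 probes matched several loci and 7239 matched none. Of 34227 probes named by accession that had a chromosome position in the files, 34140 lay within 500 bases of their locus. For 237 probes a locus code or symbol was set aside because the probe lay elsewhere or had no position. That last rule was tightened after results had been seen. Whether a probe also binds transcripts of near-identical relatives, as among the PDF1.2 genes, was not tested.

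A probe was used where it was well above background on all 4 arrays of at least 1 of the 4 groups of genotype and light, which left 28440 probes. The probe with the highest mean intensity stood for its locus, which gave 18056 genes of the 25951 loci on the array. The limma model held a WL and an FR coefficient and 1 dye term common to the 8 arrays, with 5 residual degrees of freedom, and gave 4 comparisons, namely the mutant effect in WL, in FR, as the mean of both lights, and as the FR minus WL difference. FR was compared with WL inside each genotype by limma's separate-channel model, after Aquantile scaling of the intensities, with an intraspot correlation of 0.601 and 17040 genes measured on every array. Adjusted p stands for limma's moderated test with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Errors are limma's standard errors, apart from those of the slopes on WL replicate 1. Where a probe was well above background on 0 arrays of 1 of the 2 groups compared, the ratio is given as a lower bound on the fold. Such a bound holds for the main setting only and carries no error. Where such a ratio enters an FR minus WL difference, no size is given among the comparisons. The number of arrays limits the precision of every value.

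The genes named in the text followed a rule fixed before the data were examined. It took MYC2, MYC3 and MYC4, the 10 largest rises and falls in WL and in FR among called genes with 1 sign on all 4 arrays, the 5 largest rises and falls of each other comparison, up to 4 called members of each gene list with the largest ratio, and HY5, HYH, the PIF genes, PIL1, HFR1, ATHB2 (HB-2), IAA19 and IAA29 in every case. Other list members that the text names were chosen after their values were seen. There were 27 gene lists, fixed at the same time, for the mutated genes, jasmonate biosynthesis, JAZ repressors, jasmonate turnover, jasmonate-responsive wound markers, ERF-branch defence, aliphatic and indole glucosinolate biosynthesis, glucosinolate breakdown and ER bodies, shade-induced PIF targets, PIF transcription factors, photoreceptors and photomorphogenesis regulators, flavonoid and anthocyanin biosynthesis, light-harvesting antenna and Rubisco small subunits, chlorophyll biosynthesis and greening, auxin response, cell wall loosening, brassinosteroid and gibberellin metabolism, circadian clock, salicylic acid defence, abscisic acid and cold response, heat shock proteins, touch and early stress, and tissue markers of seed, root, floral organs and guard cells. They held 362 loci, all on the array, of which 300 were tested. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and 26 lists had members to test. In the comparisons of genotype the set tests took only members measured on all 8 arrays. These were 8 of 9 JAZ repressors, 11 of 12 wound markers, 20 of 21 aliphatic, 14 of 15 shade-induced, 22 of 23 photoreceptor, 13 of 14 greening, 15 of 19 auxin, 13 of 15 cell wall, 16 of 17 clock, 11 of 13 salicylic acid, 9 of 11 touch and 3 of 4 guard cell genes, and all measured members of the other lists. Counts of fallen or risen members are of all measured ones. Camera with an estimated correlation and fry were run beside it, and list p-values are camera's at the preset correlation unless the sentence says otherwise.

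Each alternative changed 1 choice, apart from 4. The processed signals changed background and dye normalization, the deposited matrix all processing, the robust variance trend both the trend and the robust estimation, and the replicate block replaced the dye term. Alternatives covered the background correction, the processed signals, median centring, Aquantile or quantile scaling, the deposited matrix, the probe filter, the way probes of a locus were combined, the dye term, the arrays in the model, array weights, a robust variance trend, blocks by replicate number or by dye-swapped arrays, stricter thresholds, and leaving out each array in turn. A dye term per light, a background from negative controls, and a filter asking for signal in all 16 channels were added after the data had been seen. The same code was tested on simulated data with 17040 genes and the variances of the real values, 100 genes changed by 1 log2 unit and 100 by 2. It recovered 91% and 99% of them for the mutant effect in WL, 96% and 100% in FR, 97% and 100% for the mean, and 71% and 100% for the FR minus WL difference. For FR against WL it recovered 54% and 100% in Col-0 and 49% and 99% in myc2,3,4. Among the simulated calls, 3.92% to 8.80% were false. Each simulated gene had 1 variance for both lights, whereas array weights of the real data were 0.178 to 0.651 in FR and 1.09 to 9.47 in WL. The shares recovered therefore do not compare the power of the lights, and can be too high for FR. A simulated list of 20 fallen genes had an adjusted p of 1.54e-85 for the mean of both lights, and 1 of 100 random lists had an unadjusted p below 0.05. The simulated genes varied independently of each other. Estimated correlations within the real lists ran from -0.18 (root markers) to 0.767 (salicylic acid defence) in the comparisons of genotype. The random lists therefore cannot show whether list p-values hold where members vary together. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.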

Results

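MYC3 and MYC4 transcripts were strongly reduced in myc2,3,4 in both lights. This addresses whether the mutated genes were still expressed. MYC3 (chromosome 5, 18975934 to 18975993, TAIR10 per the file headers, as for all positions) fell by -3.59 ± 0.188 log2 units in WL (limma adjusted p = 8.2e-05) and by -3.40 ± 0.188 in FR (adjusted p = 0.000194). It was lower on all 4 arrays of each light, at -2.54, -4, -3.86 and -3.96 on WL replicates 1 to 4 and -3.01, -3.49, -3.27 and -3.83 on FR replicates 1 to 4. MYC4 (chromosome 4, 9933718 to 9933777) fell by -3.02 ± 0.205 in WL (-2.16, -3.39, -3.05 and -3.47; adjusted p = 0.000259) and by -2.09 ± 0.205 in FR (-2.20, -2.23, -2.29 and -1.64; adjusted p = 0.00446). A second MYC4 probe (chromosome 4, 9935232 to 9935291) gave 0.05 in WL and -0.12 in FR. The MYC2 probe (chromosome 1, 11799066 to 11799125) did not pass the threshold, at -0.46 ± 0.19 in WL (-0.47, -0.69, 0.02 and -0.69; adjusted p = 0.238) and -0.04 in FR (0.03, -1, 0.77 and 0.06; adjusted p = 0.964). Where the insertions lie relative to these probes was not given in the sources used here. As a list of 3 measured genes, the mutated genes were lower in WL (adjusted p = 4.46e-06, and 0.0351 with an estimated correlation) and in FR (adjusted p = 1.05e-04, and 0.0636 with an estimated correlation).

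In WL, glucosinolate and flavonoid genes were lower in myc2,3,4, and AG and SEP3 were among the genes that were higher. This addresses what differed in the triple mutant without added FR. The largest falls over 4 arrays were CYP79F1 (chromosome 1, 5611248 to 5611307; -5.19 ± 0.501, adjusted p = 0.00133), AK3 (-4.71 ± 0.386, 0.000534), CYP83A1 (chromosome 4, 7990683 to 7990742; -4.55 ± 0.337, 0.000334), AKN2 (-4.06 ± 0.309, 0.000373) and MAM1 (chromosome 5, 7706694 to 7706753; -4.02 ± 0.222, 0.000107). BCAT4 (-4.01 on 3 arrays), CB5-C (-3.91), CYP83B1 (-3.89), IPMI1 (-3.86) and the early light-induced gene ELIP2 (chromosome 4, 8419108 to 8419167; -3.66) completed the 10 largest falls, each lower on every array that measured it. The largest rises were AG (chromosome 4, 10388040 to 10388099; 3.28, 4.36, 3.44 and 4.62 on the 4 arrays, adjusted p = 0.000334), AT3G26470 (chromosome 3, 9686917 to 9686976; 2.79 ± 0.223, 0.000486), MRD1 (2.74 ± 0.514, 0.0255), THI2.2 (1.97), SEP3 (chromosome 1, 8593820 to 8593879; 1.95 ± 0.304, 0.0119), CER4 (1.93), AT3G56210 (1.87 on 3 arrays), AT2G32550 (1.83), AT4G23680 (1.51) and AT2G43590 (1.47). HY5 (chromosome 5, 3593637 to 3594067), a regulator of photomorphogenesis, fell by -1.24 ± 0.147 (adjusted p = 0.0032, lower on 4 of 4 arrays). Its relative HYH did not pass (-0.70, adjusted p = 0.0833). In all, 736 of 18056 genes passed, 259 higher and 477 lower. That balance turned with the model, to 2044 higher and 1998 lower with the WL arrays alone and 3337 higher and 3019 lower with array weights. Of the 736 genes, 180 changed by at least 2-fold (39 higher and 141 lower). CYP79F1 stood at -6.02 and BCAT4 at -5.21 without WL replicate 1, and CYP79F1 at -4.43, AK3 at -4.07 and IPMI1 at -3.26 without WL replicate 3. Calls were lost without at least 1 array (highest adjusted p in brackets) for MRD1 (0.0996 without WL replicate 2), SEP3 (0.0762 without WL replicate 3), AT4G23680 (0.115 without WL replicate 4) and AT2G43590 (0.104 without WL replicate 3).

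**Figure D1:**
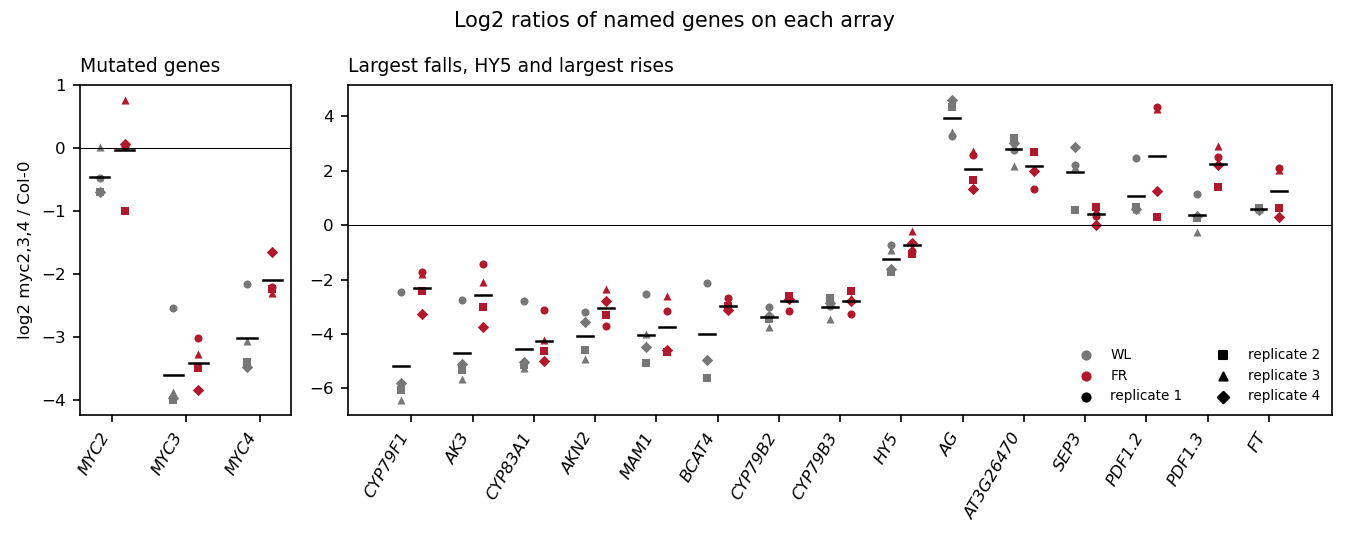
log2 ratios of myc2,3,4 over Col-0 for named genes on the 4 WL and 4 FR arrays. CYP83A1 fell by -4.55 in WL and -4.24 in FR.

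Of 21 measured aliphatic glucosinolate genes, 16 fell in WL, among them CYP79F1, CYP83A1, MAM1 and BCAT4, and 1 rose, the regulator MYB28 (0.80). The list was lower at an adjusted p of 1.29e-23 (0.0315 with an estimated correlation), its median was -2.51, and 17 members fell when adjusted over the list alone. Of 16 indole glucosinolate genes, 8 fell, including CYP83B1, CYP79B2 (chromosome 4, 18527391 to 18527450; -3.38), CYP79B3 (-2.99) and UGT74B1 (-1.80). MYB34 rose (1.03). That list was lower at an adjusted p of 1.2e-08, but not with an estimated correlation (adjusted p = 0.211). Of 14 flavonoid and anthocyanin genes, 10 fell and 0 rose, with FLS1 at -2.55, GSTF12 at -2.06, TT4 (chalcone synthase) at -2.03 and F3H at -1.87. The list was lower at an adjusted p of 1.75e-17 (0.0315 with an estimated correlation), and 13 members fell when adjusted over the list alone. Among floral organ markers, AG and SEP3 rose of 3 measured, and the list was higher (adjusted p = 1.36e-04, and adjusted p = 0.0912 with an estimated correlation). Of 8 heat shock genes, HSFA2 (-0.89) and HSP70 (-0.77) fell and the list was lower (adjusted p = 0.00224, and adjusted p = 0.361 with an estimated correlation). Of 9 brassinosteroid and gibberellin genes, GA3OX1 (-0.83) and ATGA2OX1 (-0.71) fell and the list was lower (adjusted p = 0.00766, and adjusted p = 0.124 with an estimated correlation). With 0 members past limma's threshold, 6 ERF-branch defence genes (adjusted p = 0.0344, and adjusted p = 0.604 with an estimated correlation) and 21 antenna and Rubisco genes (adjusted p = 0.0205, and adjusted p = 0.632 with an estimated correlation) were higher as lists. Calls were lost without at least 1 array for TT4 (adjusted p up to 0.147), HSFA2 (0.209), HSP70 (0.123), GA3OX1 (0.221) and ATGA2OX1 (0.156).

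Of the jasmonate genes, few passed singly in WL and no list passed by camera. Of 14 jasmonate biosynthesis genes OPR3 fell (-0.87) and the list did not pass (adjusted p = 0.702). No member passed limma's test among 9 JAZ repressors (list adjusted p = 0.971 over 8 of them, with a median of 0.05 and a mean of -0.05), 6 jasmonate turnover genes (0.986) and 12 wound markers (0.452 over 11). By fry's mixed test, which counts members moving either way, jasmonate biosynthesis (adjusted p = 0.000197), jasmonate turnover (0.000134) and the wound markers (0.0146) passed and the JAZ repressors (0.408) did not. That test does not compare a list with other genes. It passed for 18 of 26 lists in WL, so passing it does not set a list apart. In glucosinolate breakdown TGG2 rose (0.71) and BGLU18 fell (-1.30) of 11 genes, and the list did not pass (adjusted p = 0.214). Among shade-induced targets PRE1 fell (-0.51) of 15, and no PIF gene of 7 passed limma's test over all genes (list adjusted p = 0.986 for each). The PIF median was 0.03 and the mean -0.02. Adjusted over the list alone, 1 PIF gene rose. Fry's mixed test passed for the shade-induced (adjusted p = 0.0129) and PIF lists (0.00031). Of 23 photoreceptor and photomorphogenesis genes HY5 and RUP1 (-1.18) fell (list adjusted p = 0.0586). Of 14 chlorophyll and greening genes ELIP1 (-3.17) and ELIP2 fell (list adjusted p = 0.842, with a median of 0.11 and a mean of -0.41). Of 17 clock genes ELF4 (1.06) and PCL1 (0.63) rose (list adjusted p = 0.113). SAUR15 (-0.96) fell of 19 auxin genes and KIN1 (-1.29) of 11 abscisic acid and cold genes (list adjusted p = 0.842 for each, over 15 of the auxin genes). The auxin median was 0.05 with a mean of -0.07, and the abscisic acid and cold median 0.23 with a mean of -0.05. FMA (0.62) rose of 4 guard cell markers (list adjusted p = 0.452). No member passed limma's test among 15 cell wall genes (list adjusted p = 0.570 over 13), 13 salicylic acid genes (0.948 over 11), 11 touch genes (0.971 over 9) and 2 root markers (0.793). Of the seed storage list, 0 members were measured. Leaving out 1 array ended the calls of OPR3 (adjusted p up to 0.186), TGG2 (0.159), PRE1 (0.197), RUP1 (0.0657), ELF4 (0.173), PCL1 (0.223), SAUR15 (0.128), KIN1 (0.233) and FMA (0.142). The calls of ELF4 and PCL1 were lost without any 1 of 6 of the 8 arrays, and the others without fewer. The WL count was 282, 228, 173 and 248 without WL replicates 1 to 4 and 1156 without FR replicate 3. It was 1940 without background correction, 192 with processed signals, 173 with median centring, 196 without the dye term, 4042 with the WL arrays alone, 6356 with array weights, 304 with a robust variance trend, 281 with a replicate block, 1732 with random dye-swap pairs, 217 at an adjusted p below 0.01 and 180 at 2-fold.

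In FR, glucosinolate genes were again lower, PDF1.2-type defensin genes were higher and some shade-induced and cold-response genes were lower. This addresses what differed in the triple mutant under a low ratio of red to far red. The largest falls beside MYC3 were CYP83A1 (-4.24 ± 0.337, adjusted p = 0.00146), MAM1 (-3.75 ± 0.222, 0.000266), AKN2 (-3.04 ± 0.309, 0.0047), BCAT4 (-2.96 ± 0.369, 0.0142), CYP79B3 (chromosome 2, 9490897 to 9490956; -2.78 ± 0.13, 0.000114) and CYP79B2 (-2.78 ± 0.139, 0.000114), each lower on 4 of 4 arrays. AK3 (-2.57), CB5-C (-2.45) and DJ1F (-2.36) fell as well. The largest rises were PDF1.2 (chromosome 5, 17907181 to 17907240; 2.55 ± 0.414, adjusted p = 0.0295), PDF1.3 (chromosome 2, 11087435 to 11087596; 2.25 ± 0.236, 0.00533), AT3G26470 (2.19), AG (2.08 ± 0.293, 0.016), PDF1.2c (2.05), PGL5 (chromosome 5, 8336957 to 8337016; 1.89), PDF1.2b (1.83), AT3G56210 (1.56) and AT1G03020 (1.28). FT (chromosome 1, 24333506 to 24333565), a promoter of flowering, rose (adjusted p = 0.0341, higher on 4 of 4 arrays), with Col-0 below background in FR. Its bound of 2.40-fold is the ratio of the mean signals in the main setting and not a least size over settings. Over the other settings its log2 ratio ran from 0.692 to 3.29. HY5 (-0.72, adjusted p = 0.0635) and HYH (-0.43, adjusted p = 0.364) did not pass. In all, 201 of 18056 genes passed, 42 higher and 159 lower. Of these, 79 changed by at least 2-fold (18 higher and 61 lower). Each gene had 1 spread for both lights, but array weights were 0.178 to 0.651 on FR arrays and 1.09 to 9.47 on WL arrays. Errors and p-values can thus be too small in FR and too large in WL. With the FR arrays alone 59 genes passed in FR, and with array weights 39. The mutant signal of MYC3, MYC4, CYP83A1, MAM1, AKN2, BCAT4, CYP79B2, CYP79B3, AK3 and CB5-C was well above background on 2 of 4 FR arrays. So was the Col-0 signal of PDF1.3, AT3G26470, AG, PDF1.2c, PDF1.2b and AT1G03020. Calls were lost without at least 1 array for PDF1.2 (adjusted p up to 0.134), AG (0.0931), PDF1.2c (0.0931), AT1G03020 (0.0511), FT (0.136), BCAT4 (0.0918), AK3 (0.12) and CB5-C (0.0515), each highest without FR replicate 1 except AK3 (FR replicate 4).

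Of 21 aliphatic glucosinolate genes 9 fell and 0 rose in FR, among them CYP83A1, MAM1, BCAT4 and IPMI2 (-2.09), and 16 fell when adjusted over the list alone. The list was lower (adjusted p = 3.96e-14), though not with an estimated correlation (adjusted p = 0.0636). Of 16 indole genes CYP79B3, CYP79B2 and UGT74B1 (-1.21) fell and MYB51 rose (1.22), with the list lower (adjusted p = 3.18e-04, and adjusted p = 0.319 with an estimated correlation). The 4 measured PDF genes rose of 6 ERF-branch genes, and the list was higher (adjusted p = 2.58e-06, and adjusted p = 0.202 with an estimated correlation). Of 15 shade-induced targets FHL (-1.19), PAR2 (-0.84) and PAR1 (chromosome 2, 17836786 to 17836845; -0.82) fell and 8 fell when adjusted over the list alone. The list was lower (adjusted p = 3.59e-06, and adjusted p = 0.0636 with an estimated correlation). PIL1 (-0.78, adjusted p = 0.125), HFR1 (-0.56, adjusted p = 0.119), HB-2 (-0.16), IAA19 (0.02) and IAA29 (0.18) did not pass. Of 11 abscisic acid and cold genes COR15A (-1.71), LTI78 (-1.48), COR47 (-0.77) and ERD10 (-0.71) fell, with the list lower (adjusted p = 9.85e-04, and adjusted p = 0.319 with an estimated correlation). AG rose of 3 floral markers (list adjusted p = 0.00511, and adjusted p = 0.202 with an estimated correlation). With 0 members past limma's threshold, 8 heat shock genes (adjusted p = 0.00202, and adjusted p = 0.319 with an estimated correlation) and 11 salicylic acid genes (adjusted p = 0.0119, and adjusted p = 0.583 with an estimated correlation) were higher as lists, and 13 cell wall genes were lower (adjusted p = 0.0061, and adjusted p = 0.319 with an estimated correlation). Leaving out 1 array ended the calls of MYB51 (adjusted p up to 0.129), UGT74B1 (0.0534), FHL (0.0651), PAR2 (0.0599), PAR1 (0.0715), LTI78 (0.128), COR47 (0.0634) and ERD10 (0.148). The call of ERD10 was lost without any 1 of the 8 arrays and that of LTI78 without any 1 of 6. The others were lost without fewer arrays.

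The flavonoid list did not pass in FR (adjusted p = 0.0791), with 0 of 14 members past limma's threshold and 4 lower and 1 higher when adjusted over the list alone. No member passed limma's test over all genes among clock genes (list adjusted p = 0.0791), jasmonate biosynthesis (0.188), JAZ repressors (0.295), jasmonate turnover (0.148), wound markers (0.479), photoreceptors (0.481, with a median of 0.01 and a mean of -0.10), antenna and Rubisco genes (0.436), root markers (0.674) and guard cell markers (0.779). Adjusted over the list alone, 3 jasmonate biosynthesis genes were higher and 1 lower, 1 turnover gene was higher and 2 lower, and members of other lists passed too. By fry's mixed test jasmonate biosynthesis (adjusted p = 0.00266), turnover (0.00225) and the wound markers (0.0096) passed and the JAZ repressors (0.142) did not. In FR that test passed for 17 of 26 lists. ESP rose (1.04) in the breakdown list (adjusted p = 0.167), and PIL2 fell (-0.76, below background in WL) among the PIF genes (0.755). ELIP1 fell (-1.66) among greening genes (0.914) and GA3OX1 fell (-1.08) among brassinosteroid and gibberellin genes (0.167). SAUR15 (-1.06) and SHY2 (-0.56) fell among auxin genes (list adjusted p = 0.295, with a median of 0.02 and a mean of -0.05). DREB1A (-1.36) and CBF1 (-1.14) fell among touch genes (0.295, with a median of 0.26 and a mean of -0.01). Leaving out 1 array ended the calls of ESP (adjusted p up to 0.126), PIL2 (0.185), ELIP1 (0.179), GA3OX1 (0.114), SAUR15 (0.136), SHY2 (0.17) and CBF1 (0.124). The call of SHY2 was lost without any 1 of the 8 arrays, and those of ESP, PIL2 and GA3OX1 without any 1 of 6. The others were lost without fewer arrays. The FR count was 52, 69 and 79 without FR replicates 1, 2 and 4, and 119 and 114 without WL replicates 2 and 3. It was 93 with processed signals, 63 with median centring, 45 without the dye term, 59 with the FR arrays alone, 39 with array weights, 37 with a robust variance trend, 81 with a replicate block, 704 with random dye-swap pairs, 373 with 1 dye term per light, 60 at an adjusted p below 0.01 and 79 at 2-fold. With the robust variance trend 0 genes were higher, so none of the rises, those of the PDF genes, AG and FT included, passed there.

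**Figure D2:**
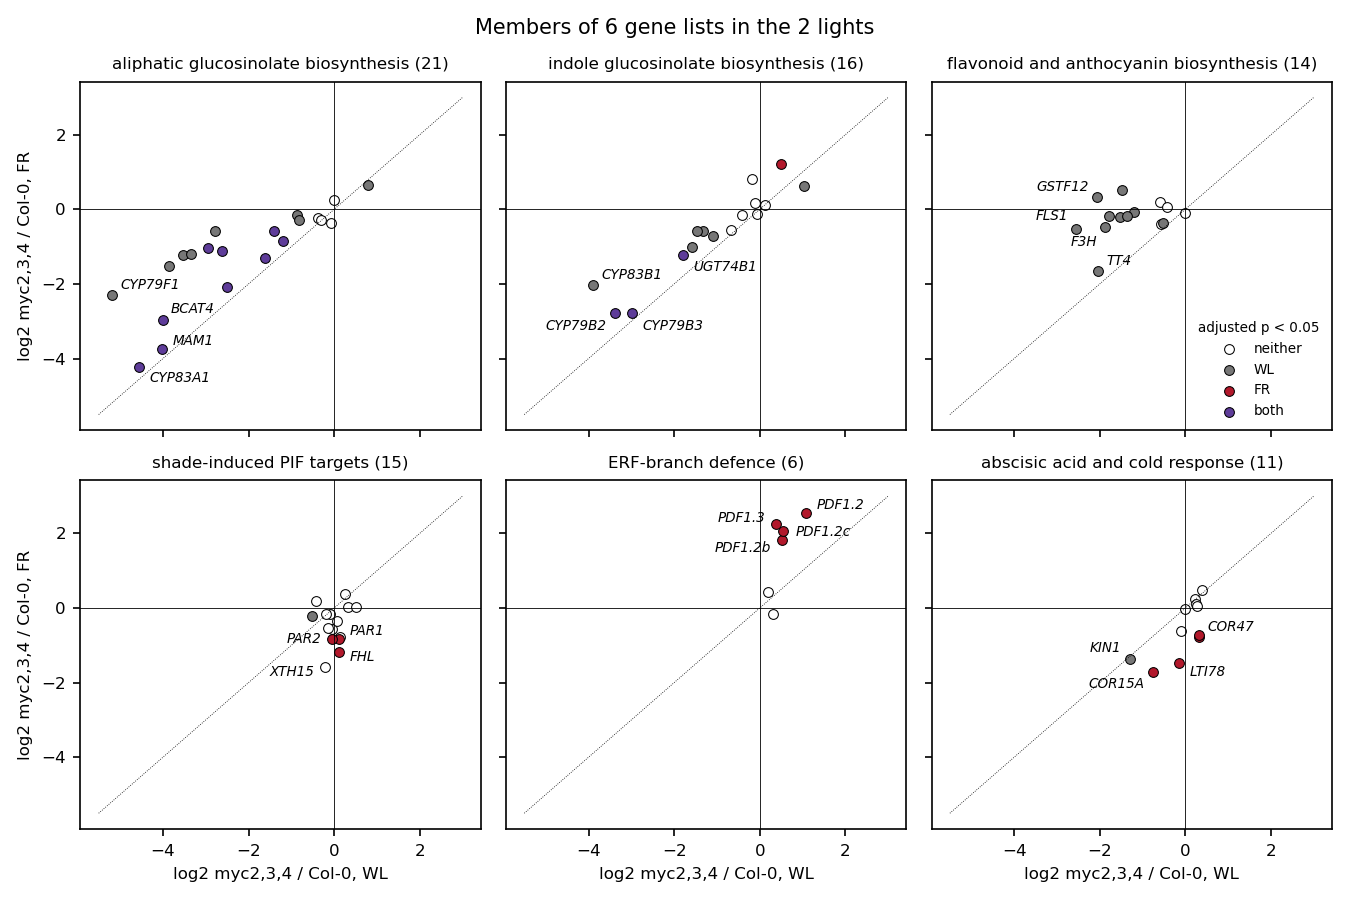
Effects of myc2,3,4 on the gene lists in WL and FR. The aliphatic glucosinolate list was lower at an adjusted p of 1.29e-23 in WL and 3.96e-14 in FR.

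The mutant effect pointed the same way in both lights for most genes that passed in WL. This addresses how far the mutant acts alike in the 2 lights. Of the 736 WL genes, 595 (80.8%) had the same sign in FR. Across all genes the effects correlated at r = 0.458 (rho = 0.341). Genes lower in both lights numbered 78 against 4.2 expected, genes higher in both 10 against 0.60, and 2 had opposite signs. With median centring these were 27 lower and 6 higher (0.319 and 0.044 expected), and without the dye term 28 and 4 (0.305 and 0.0208 expected). The expected numbers take the calls of the lights as independent. Both lights shared 1 spread per gene, so the excess over them can be overstated. For the mean of both lights, 1026 genes passed, 373 higher and 653 lower. CYP79B2 fell by -3.08 ± 0.0986 (adjusted p = 3.88e-06), MAM1 by -3.89 ± 0.157 (1.09e-05), CYP83A1 by -4.40 ± 0.239 (6.54e-05), HY5 by -0.98 ± 0.104 (0.00169) and HYH by -0.57 ± 0.133 (0.0455) over 8 arrays. AG rose by 3.00 ± 0.207 (adjusted p = 0.000194), AT3G26470 by 2.49 ± 0.158 (0.000125) and PGL5 by 1.63 ± 0.119 (0.000249). Among jasmonate genes OPR3 (-0.74, adjusted p = 0.0132), ILL6 (-0.59, 0.0112), VSP1 (-0.84, 0.0481) and VSP2 (-0.75, 0.0151) fell, while LOX3 (0.27, 0.0452), LOX4 (0.34, 0.0413), JAZ6 (0.43, 0.037) and CYP94C1 (0.53, 0.0181) rose. Their lists did not pass by camera, at adjusted p = 0.225 for biosynthesis, 0.557 for JAZ repressors, 0.456 for turnover and 0.921 for wound markers. PIF7 rose (0.32, adjusted p = 0.023) and the PIF list did not pass (adjusted p = 0.681). Of the lists, the mutated genes (adjusted p = 1.75e-05, and 0.0446 with an estimated correlation), aliphatic glucosinolates (16 of 21 lower, adjusted p = 1.03e-20, and 0.0446 with an estimated correlation) and flavonoids (11 of 14 lower, adjusted p = 2.74e-12, and 0.0446 with an estimated correlation) were lower in the mean. The indole (adjusted p = 2.34e-06, and adjusted p = 0.228 with an estimated correlation), shade-induced (0.00264; 0.0809), brassinosteroid and gibberellin (0.00975; 0.118) and cell wall lists (0.0405; 0.415) were lower as well. The ERF-branch (adjusted p = 4.02e-05, and adjusted p = 0.224 with an estimated correlation), floral (0.000178; 0.0809) and clock lists (0.0298; 0.228) were higher. The mean count was 672, 638, 1554 and 680 without FR replicates 1 to 4 and 515, 446, 345 and 524 without WL replicates 1 to 4. It was 1681 without background correction, 383 with processed signals, 217 with median centring, 230 without the dye term, 368 with a robust variance trend, 413 with a replicate block, 2329 with random dye-swap pairs, 292 at an adjusted p below 0.01 and 98 at 2-fold.

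As lists at the preset correlation, flavonoid and aliphatic glucosinolate genes fell less in the mutant in FR than in WL. This addresses whether the mutant effect depends on the light. The FR minus WL difference was positive for GSTF12 (chromosome 5, 5658741 to 5658885; 2.38 ± 0.336, adjusted p = 0.0339), BAT5 (chromosome 4, 7212404 to 7212463; 2.32 ± 0.323, 0.0339) and AT5G62210 (2.06 ± 0.314, 0.0449), over 8 arrays. In FR, GSTF12 and BAT5 were well above background on 2 of 4 arrays in each genotype. Negative differences included AT2G32550 (-1.73 ± 0.24, adjusted p = 0.0339), GolS3 (-1.37 ± 0.153, 0.0195), GPAT3 (-1.31 ± 0.164, 0.0305) and ACS4 (-1.15 ± 0.165, 0.0346). ELIP2, GSTF11 and AT5G02580 passed as well, but no size is given for them. ELIP2 and GSTF11 were well above background in the mutant on 0 of 4 FR arrays, and AT5G02580 in both genotypes on 0 of 4 WL arrays. In all, 54 of 18056 genes passed, 42 with a positive and 12 with a negative difference. Of 14 flavonoid genes 5 passed, all positive, including FLS1 (2.03) and F3H (1.39), and the list was positive (adjusted p = 5.91e-15, and adjusted p = 0.0703 with an estimated correlation). FLS1 and F3H were not well above background in all 16 channels. Of 21 aliphatic genes BAT5, GSTF11 and 2 others passed, all positive, and the list was positive (adjusted p = 1.3e-12, and adjusted p = 0.0843 with an estimated correlation). With probes above background in all 16 channels the median difference was 1.13 for the flavonoid list and 0.29 for the aliphatic list, against 1.16 and 0.55 with all probes used. Most genes of both lists were also lower in FR than in WL in Col-0, which left less signal for a further fall in the mutant. How far that limits the FR ratios was not tested beyond this filter. HSP70 passed (1.45) of 8 heat shock genes, with the list positive (adjusted p = 1.87e-06, and adjusted p = 0.186 with an estimated correlation). COR47 passed (-1.10) of 11 abscisic acid and cold genes, with the list negative (adjusted p = 6.05e-04, and adjusted p = 0.295 with an estimated correlation). With 0 members past limma's threshold, the shade-induced list was negative (adjusted p = 8.37e-05, and adjusted p = 0.0769 with an estimated correlation). Likewise with 0 members past limma's threshold, the indole (adjusted p = 4.55e-05, and adjusted p = 0.325 with an estimated correlation) and ERF-branch lists (adjusted p = 0.00126, and adjusted p = 0.325 with an estimated correlation) were positive. The antenna and Rubisco list (adjusted p = 0.00629, and adjusted p = 0.498 with an estimated correlation) and the floral list (adjusted p = 0.0119, and adjusted p = 0.276 with an estimated correlation) were negative, with 0 members past limma's threshold in each. HY5 (0.52, adjusted p = 0.435), AG (-1.84, 0.154) and PDF1.3 (1.87, 0.0783) did not pass, so a light-dependent mutant effect was not shown for them. For each of the 5 most positive and 5 most negative differences, those with no size included, the call was lost on leaving out any 1 of at least 6 of the 8 arrays (adjusted p up to 0.16). The count by limma was 0 without FR replicates 1, 2 or 4 or WL replicates 2, 3 or 4 (unadjusted p below 0.05 for 2037, 1822, 1605, 1354, 1212 and 1500 genes) and 25 without WL replicate 1. It was 237 without background correction, 235 with random dye-swap pairs, 97 with 1 dye term per light, 1 with processed signals, 1 with median centring, and 0 by limma without the dye term (unadjusted p below 0.05 for 759 genes), with a robust variance trend (1800), with a replicate block (1278) or at an adjusted p below 0.01 (1857).

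Shade-induced, auxin, flavonoid and aliphatic glucosinolate genes differed between FR and WL in both genotypes. This addresses how the FR and WL samples differed in Col-0 and in the mutant. Each slide and scan held 1 light, so the light and the slide cannot be told apart in these values. The hour of harvest was not given, so light and hour cannot be told apart either if the hours differed. In Col-0 large rises were those of AT2G33830 (7.50 ± 0.25), PAR1 (7.26 ± 0.166), ST2A (7.13 ± 0.458, well above background on 1 of 4 WL arrays), XTH15 (6.90 ± 0.705) and DYL1 (6.67 ± 0.197). Large falls were those of ELIP2 (-7.55 ± 0.347, well above background on 1 of 4 FR arrays), AT2G27420 (-7.55 ± 0.341, on 2 of 4), F3H (-6.53 ± 0.315) and FLS1 (-6.30 ± 0.222). AT1G24580 fell by at least 61.1-fold (adjusted p = 7.07e-12), a lower bound because it was well above background on 0 of 4 FR arrays. In myc2,3,4 ADS1 rose by 6.98 ± 0.26 and AT2G16660 by 6.44 ± 0.304, while AT5G42760 fell by -5.55 ± 0.341 (well above background on 2 of 4 FR arrays) and APR3 by -5.22 ± 0.294. PIL1 (chromosome 2, 19295572 to 19295631) rose by 6.19 ± 0.263 in Col-0 (adjusted p = 1.95e-11) and 5.27 in the mutant. HFR1 (chromosome 1, 465948 to 466007) rose by 4.42 and 3.91, HB-2 by 4.57 and 4.50 and IAA19 by 3.46 and 2.98. HY5 fell by -3.59 ± 0.23 (adjusted p = 1.99e-09) and -3.07, and HYH by -5.49 and -5.22. Of the PIF genes, PIF3 (1.21 in Col-0), PIF4 (1.17) and PIL2 (at least 16.3-fold, well above background on 0 of 4 WL arrays) rose, UNE10 (-3.59) and PIF7 (-2.56) fell, and PIL5 (-0.42, adjusted p = 0.0569) and PIL6 (-0.15, adjusted p = 0.59) did not pass.

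Of 14 shade-induced targets 12 rose and 1 fell in Col-0 (list adjusted p = 9.8e-10, and 5.65e-04 with an estimated correlation). In the mutant 13 rose (1.55e-09, and 6.2e-04 with an estimated correlation). Of 15 auxin genes 12 rose and 1 fell in Col-0 (list adjusted p = 5.67e-06, and 0.0257 with an estimated correlation). Of 14 flavonoid genes 12 fell in Col-0 (list adjusted p = 2.68e-06, and 0.0395 with an estimated correlation) and 9 in the mutant (adjusted p = 0.00144, and adjusted p = 0.246 with an estimated correlation). Of 20 aliphatic glucosinolate genes 19 fell in Col-0 (list adjusted p = 7.4e-08, and adjusted p = 0.093 with an estimated correlation) and 11 in the mutant (adjusted p = 0.00102, and adjusted p = 0.448 with an estimated correlation). Of 16 indole genes 6 rose and 3 fell in Col-0 (list adjusted p = 0.795, with a median of -0.05 and a mean of 0.14) and 7 rose and 2 fell in the mutant (list adjusted p = 0.0988), so that list did not pass. In the mutant 13 auxin genes rose (list adjusted p = 5.4e-07, and 0.0118 with an estimated correlation). Of 9 touch genes 7 rose in Col-0 (list adjusted p = 0.00496, and adjusted p = 0.401 with an estimated correlation), and of 8 heat shock genes 6 fell (list adjusted p = 0.013, and adjusted p = 0.401 with an estimated correlation). In the mutant the touch list (adjusted p = 0.00102, and adjusted p = 0.4 with an estimated correlation) and the ERF-branch list (adjusted p = 0.0309, and adjusted p = 0.648 with an estimated correlation) were higher. Of 16 clock genes 8 rose and 8 fell in Col-0, with PRR5 at least 94.5-fold higher (well above background on 0 of 4 WL arrays), TOC1 at 2.91, LHY at -4.96 and CCA1 at -4.14, and the list did not pass (adjusted p = 0.844, with a median of -0.06 and a mean of 0.15). In all, 8388 of 17040 genes passed in Col-0 (4047 higher and 4341 lower) and 7812 in myc2,3,4 (3687 higher and 4125 lower). Without Aquantile scaling the share of higher calls moved from 48.2% to 82.4% in Col-0 and from 47.2% to 83.2% in the mutant. The median of all genes moved from -0.04 to 0.58 log2 units in Col-0 and from -0.07 to 0.56 in the mutant, so the balance of higher and lower genes rests on the scaling. At 2-fold the counts were 4259 and 3880.

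**Figure D3:**
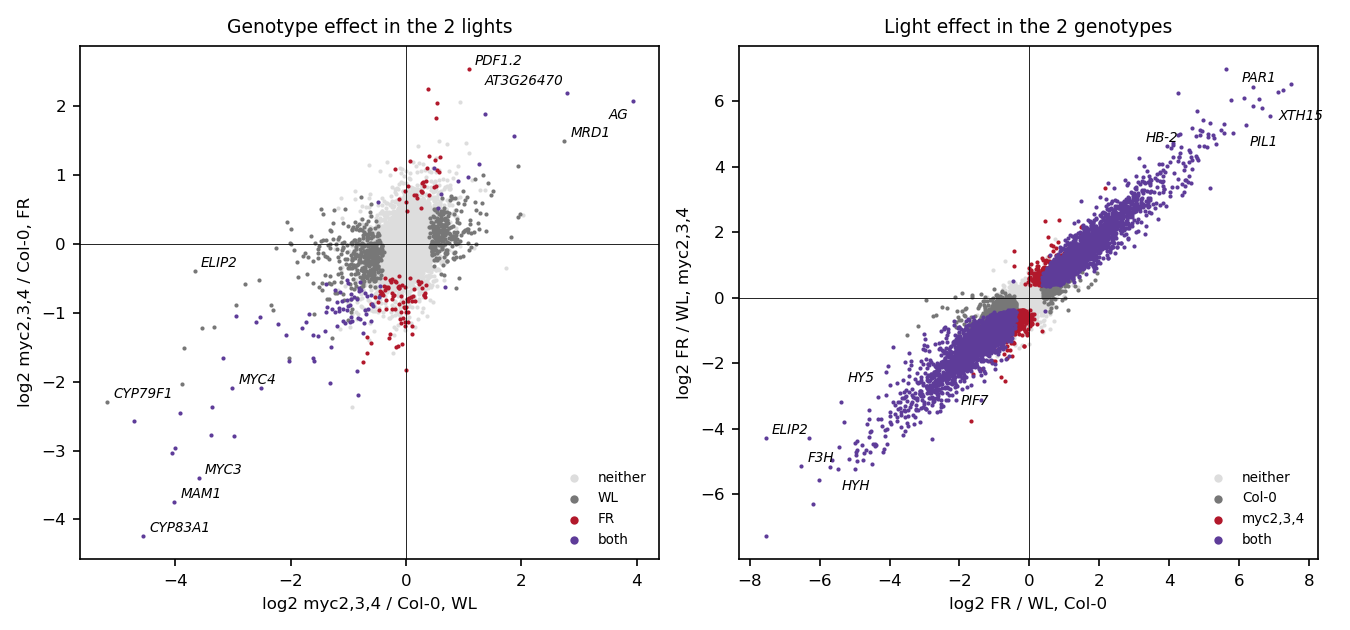
Effects of myc2,3,4 on all 18056 genes in WL against FR, and effects of the light in the 2 genotypes. Of 736 genes that passed in WL, 595 had the same sign in FR.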

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

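The slide test and the way the tests of Col-0 RNA, of compressed ratios and of floral tissue were read were chosen after results were seen, and so were the use of Hyper5 alone and the spread it was held to. Of 211 groups of 4 arrays examined for an array far from the others, 12 had such an array, against 10.6 expected by chance at 1 in 20, so these values as a set can be chance. The array far from the others was FR replicate 4 for Hyper5 spots well above background (33392). It was WL replicate 1 for CYP79F1 (log2 ratio -2.47), CYP83A1 (-2.80), PDF1.2 (2.48) and MYC3 (-2.54), WL replicate 2 for TT4 (-1.49), and WL replicate 3 for BGLU18 (-1.79) and ATGA2OX1 (-0.46). It was FR replicate 3 for PIL1 (-1.71), PIL6 (-0.15) and ESP (1.87), and FR replicate 4 for MYC4 (-1.64).

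The mutant effect differed between FR and WL for 54 genes by limma. The named ones were ELIP2 (3.27), GSTF12 (2.38), BAT5 (2.32), GSTF11 (2.21), AT5G62210 (2.06), FLS1 (2.03), HSP70 (1.45), F3H (1.39), AT5G02580 (-1.83), AT2G32550 (-1.73), GolS3 (-1.37), GPAT3 (-1.31), ACS4 (-1.15) and COR47 (-1.10), all as fitted log2 FR minus WL. Those of ELIP2, GSTF11 and AT5G02580 rest on ratios at background in 1 light and are not measured sizes. A value in data not analysed for genes was the share of channel readings well above background among 7737 probes with no single locus, 36.3% against 0.817% at 153 negative controls. Of these probes 2598 passed the filter, and limma called 76 in WL (18 higher and 58 lower) and 35 in FR (7 higher and 28 lower).

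Flavonoid and aliphatic glucosinolate genes fell less in FR than in WL, with a median difference of 1.16 and 0.545 log2 units. The Cy3 negative-control signal was 1506 to 1701 on the FR slide against 62.2 to 63.5 on the WL slide, so a raised Cy3 background might shrink the FR falls. A first test with a negative-control background was void, because the normexp step estimates the background again, and was replaced. With Hyper5 signals alone the differences were 0.976 (SD over members 0.786) for flavonoid and 0.983 (SD 1.08) for aliphatic genes, and over all genes these effects correlated with those of both dyes at r = 0.683 in WL and 0.47 in FR. The flavonoid difference exceeded its SD and the aliphatic difference did not. This SD shows how members differ and is not an error of the median. Hyper5 alone also compares the genotypes between arrays, and no error of that comparison was estimated. Both lists still fell less in FR with no Cy3 signal used. Low Col-0 signals of these genes in FR can limit the falls with Hyper5 alone as well, which was not tested. Without an error for these values, how much the Cy3 background adds stays open for both lists. Slides that held both lights numbered 0, so slide or scan in place of the light remains open beside a biological effect of the light. With the hour of harvest not given, a difference in hour between the lights is not told apart either.

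Falls in the mutant were smaller on WL replicate 1 than on the other WL arrays, among them those of CYP79F1 and MYC3. Col-0 RNA in the mutant sample might cause this, and so might ratios compressed over the whole array. The slope of falls against the fit of the other 7 arrays was 0.677 ± 0.021 (0.914 to 1.23 on the other WL arrays), and the slope of rises was 0.688 ± 0.049 (0.844 to 0.856). These errors come from resampling the genes on 1 array, not from limma or from other arrays, and can be too small where genes vary together. A share of 12.7% Col-0 RNA, fitted on the falls, would put the slope of rises at 0.776 to 0.787, and compression as strong as that of the falls at 0.465 to 0.634. Within 2 standard errors the slope of rises (0.590 to 0.786) reaches both, so the 2 explanations cannot be told apart. Single genes differed, with PDF1.2 higher on WL replicate 1 (2.48) than on the other WL arrays (0.59 to 0.68) and falls over 2 log2 units needing a median share of 11.9% (quartiles 6.31% and 14.9%).

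AG and SEP3 were higher in the mutant in WL, which might reflect floral tissue in the mutant samples, variation linked to the mutated loci, or regulation by the MYC proteins. Of the other 5 floral organ markers 0 were higher by limma with no filter, but AP1, AP3, PI and SEP2 were well above background on at most 2 of 4 mutant WL arrays. The 1 marker well above background on all 4, SEP1, stood at 0.57 (adjusted p = 0.233, well above background on 1 Col-0 array), so floral tissue stays open. AG lies 454.3 kb from MYC4. Within 1 Mb of MYC2, MYC3 or MYC4, 48 of 926 genes (5.18%) were called in the mean of both lights against 976 of 17123 elsewhere (5.70%), with an odds ratio of 0.904 (95% interval 0.657 to 1.22, Fisher exact p = 0.56). This leaves an effect of linkage on AG alone open, and regulation by MYC was not tested.

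Whether counts this large arise when the arrays are grouped at random was examined by exchanging labels. For WL (736, highest other 37) and FR (201, highest other 30) there were only 8 splits each, too few for a share under 0.05. For the mean of both lights (1026, highest other 374) 1 of 100 splits was as large, so a random exchange of labels on these arrays rarely gives such a count. If replicates were repeat hybridizations, this does not cover chance between plants. For FR against WL in Col-0 (8388, highest other 12) and in the mutant (7812, highest other 12) 1 of 34 splits was as large. That split was the real one, which also parts the slides, so chance differences between slides are not excluded. For the FR minus WL difference 1 of 34 splits was as large (54, highest other 50), the smallest share that 34 splits can give. With the highest other so close, and a count of 0 without FR replicate 1 and in other settings, chance is not excluded there. In the splits by light, the real split is also that of the slides, so light and slide are not told apart.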

How the results depend on the processing

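The dye term per light, the negative-control background and the filter for all 16 channels were chosen after results were seen. No called value of a named gene changed sign in any setting. Lists were tested only by fry and camera, with processed signals, median centring, the replicate block, the 3 added settings and each array left out, and none past camera's threshold changed sign there. In all, 47 of 114 called values of named genes stayed past the threshold in every setting. The array number limits what could be detected. In FR the Cy3 signal over background (at most 1.55 times the negative controls, against at least 5.20 in WL) may limit it too, which was not tested. A dye effect (SD 0.352 log2 over genes, past the threshold for 6873 genes) exceeded the genotype effect (SD 0.248). Turned ratios of opposite-dye arrays therefore correlated between -0.099 and 0.031 in WL and between -0.509 and -0.344 in FR.

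Counts follow as WL, FR, mean of both lights and FR minus WL difference, against 736, 201, 1026 and 54, and the cause was not tested except where the setting tests fewer arrays or a stricter threshold. They were 192, 93, 383 and 1 with processed signals, 173, 63, 217 and 1 with median centring, and 196, 45, 230 and 0 without the dye term. They were 304, 37, 368 and 0 with a robust variance trend (0 higher in FR) and 217, 60, 292 and 0 at an adjusted p below 0.01. With arrays 1 and 2, and 3 and 4, as random blocks they were 1732, 704, 2329 and 235, at an estimated correlation of -0.300. Without background correction WL, mean and difference were 1940, 1681 and 237, and with array weights (0.178 for FR replicate 3 to 9.47 for WL replicate 3) WL and FR were 6356 (3337 higher) and 39. With the 4 arrays of the light alone WL and FR were 4042 (2044 higher) and 59, at 2-fold WL, FR and mean were 180, 79 and 98, and with 1 dye term per light FR and difference were 373 and 97. For the 0 counts by limma, an unadjusted p below 0.05 was reached by 759 genes without the dye term, 1800 with a robust variance trend and 1857 at the stricter threshold. Leaving out each array gave 173 to 1156 genes in WL, 52 to 293 in FR, 345 to 1554 for the mean and 0 to 49 for the difference. FR against WL gave 4259 genes in Col-0 and 3880 in the mutant at 2-fold, and 7198 to 8371 and 6684 to 7679 when each array was left out.

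With the replicate number as a block (the replicate block) the counts were 281, 81, 413 and 0 (unadjusted p below 0.05 for 1278 genes). Deviations of arrays with the same number correlated at 0.447 to 0.590, but these arrays share their dyes. FR1 correlated higher with WL3 (0.629) than with WL1 (0.476), and FR4 higher with WL2 (0.506) than with WL4 (0.447). The other FR arrays went the other way, FR2 with 0.590 for WL2 and 0.520 for WL4, and FR3 with 0.484 for WL3 and 0.445 for WL1. After the dye term the same-number values were -0.588 to -0.307. The fit itself forces same-dye arrays of the 2 lights to deviate in opposite directions, so these values cannot decide. Whether samples were paired by number stays open, and the unpaired model was kept.

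Lists past the threshold numbered 9 in WL, 10 in FR, 10 for the mean, 9 for the difference and 6 in each genotype for FR against WL. With an estimated correlation they were 3, 0, 3, 0, 3 and 2 (unadjusted p below 0.05 for 5 in FR and 4 for the difference). Fry mixed gave 18, 17 and 20 for WL, FR and mean, and 20 and 21 for FR against WL in Col-0 and the mutant, and fry directional gave 3 for the difference and 16 and 19 for FR against WL. With probes above background in all 16 channels WL, FR and mean gave 5, 6 and 6. The brassinosteroid and gibberellin list in FR against WL in Col-0 was higher by camera (adjusted p = 0.848) and lower by fry (adjusted p = 0.00409). A slide or scan block was not run, since each slide held 1 light.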

Other observations

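Clock genes differed between FR and WL in both genotypes, with CCA1 (-4.14 in Col-0 and -4.05 in myc2,3,4), LHY (-4.96 and -4.70) and RVE8 (-3.69 and -3.38) lower and PRR5 (at least 94.5-fold in Col-0, with 0 of 4 WL arrays well above background, and 6.06 in myc2,3,4), TOC1 (2.91 and 2.85), ELF4 (4.56 and 3.72) and PCL1 (4.27 and 3.61) higher in FR. These members were chosen after their values were seen. The hour of harvest was not given in the sources used here, so whether these values reflect the light or the hour cannot be told.

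Among regulators of glucosinolate synthesis, MYB28 (0.80) and MYB34 (1.03) rose in WL and MYB51 rose in FR (1.22). MYB29 (-0.07 in WL and -0.37 in FR) and MYB76 (-0.39 and -0.23) did not pass, and regulators were not tested as a group. PHYA rose in FR against WL by 3.12 in Col-0 and 2.02 in myc2,3,4.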
